A study of Mus musculus with 15 samples.

How the data were processed

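The series holds 15 arrays in 5 groups of 3: WT iNKT cells of stage 1-2, WT iNKT cells of stage 3, KO iNKT cells, WT T cells and KO T cells, all sorted from thymi of 4-week-old mice. Per the labels, total RNA was reverse transcribed, amplified, labelled with biotin and hybridised to single-colour Illumina mouse bead arrays. The authors deposited a table that the file headers call non-normalized, with GenomeStudio (no version stated) as the named tool. Per the file headers it holds the average signal of each probe as a linear intensity, without background subtraction, and a detection p-value for each probe and array. A second deposited table holds intensity values that the authors normalized between arrays; its arrays have nearly equal quartiles, and it was used as an alternative alone. Each array in one table had a rank correlation of 1 with its own column in the other, and no array was identical to another. The groups were taken from the sample titles.

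Of 25697 probes 23978 carried 1 gene symbol, for 16593 symbols, and 1719 unnamed probes were not used here. Gene names were checked against a RefSeq gene table, in which the gene identifiers of 16 named probes were missing. Intensities were corrected for background, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with an offset of 16. A probe was kept when its detection p-value was under 0.05 on all 3 arrays of at least 1 group, and each gene was represented by its kept probe with the highest mean log2 intensity, which left 6838 genes. A limma model with a mean per group was fitted over all 15 arrays (10 residual degrees of freedom), followed by contrasts and eBayes. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, two-sided. For a gene detected on no array of the lower group, the fold is given as a lower bound against the detection limit of that group and is written as at least that many fold. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

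The contrasts were KO iNKT against WT stage 1-2 and against WT stage 3, the genes changed the same way in both, KO T against WT T, WT stage 3 against WT stage 1-2, the mean of both WT iNKT groups against WT T, and the difference of the KO effects in iNKT cells (against WT stage 1-2) and T cells. The contrasts, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where the closing section says otherwise. The rule named, in each contrast, the 6 rising and 6 falling genes with the largest log2 change among those that passed, provided that all arrays of one side lay above all arrays of the other and that the symbol was not a clone or predicted-gene name. For the difference of the effects it named the 5 largest each way, and for the genes changed against both stages the 6 each way with the largest smaller change. It added up to 3 members with the smallest adjusted p of each list described, and Dicer1.

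For 29 gene lists, written from textbook knowledge of these cells and of other cells a thymic sort could hold, members past the threshold were counted over all genes and adjusted over the list alone. Each list was tested with camera of limma, two-sided, with a preset correlation between genes of 0.01 and again with an estimated correlation, and adjusted over the lists of a contrast. Lists overlap, and no list was chosen on these samples. For the stage axis, genes were chosen on 2 arrays of each WT iNKT stage, and the remaining WT arrays and the KO arrays were placed on it; each position is a mean over 3 rounds. Within-group deviations were checked for pairing by replicate number: of 30 same-number pairs between groups 3 correlated above 0.1 (range -0.233 to 0.481). For 2 of 15 arrays the mean correlation with arrays of the other groups was highest for their own number. The numbers were therefore not taken to pair the samples.

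The alternatives were quantile normalization without background correction, median scaling, the authors' normalized table, no detection filter and a stricter one (0.01), every probe tested, a fold change of at least 2, eBayes with trend and robust, the compared groups alone, the replicate number as a block, array weights, other WT iNKT references, and each array left out in turn. The steps were tested on simulated data of 6838 genes with 50 changed genes per fold size. In the contrast of KO iNKT with WT stage 1-2 cells, 6%, 56%, 96% and 98% of genes changed 1.5-fold, 2-fold, 3-fold and 4-fold were recovered, and in that of the T cells 10%, 54%, 96% and 100%. Of 6638 unchanged genes 5 and 6 were called. In the simulated data camera called the shifted list and 0 others, and a simulated axis position of 0.4 was recovered as 0.405. The simulated genes were independent of each other, so the camera result does not test the preset correlation. A test of microRNA seed sites was not run, because no 3′UTR sequences were at hand, and no genome coordinates are given.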

Results

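Gene expression was measured on 15 single-colour Illumina mouse bead arrays, 3 for each of 5 groups of thymic cells sorted from 4-week-old mice. Dicer is the RNase that makes mature microRNAs from their precursors. In the knock-out (KO) mice a Cre recombinase under the CD4 promoter deletes floxed Dicer alleles in developing thymocytes, and the wild-type (WT) mice carried the same alleles without Cre. Invariant NKT (iNKT) cells are T cells that recognise lipids presented by CD1d, and they were sorted as cells low for HSA, intermediate for TCRβ and positive for the CD1d tetramer. WT iNKT cells were split into the less mature stage 1-2 (negative for NK1.1) and the mature stage 3 (positive for NK1.1 and high for CD44). KO iNKT cells were not split by stage. T cells from both genotypes were low for HSA, positive for TCRβ and negative for the CD1d tetramer. The labels do not say that the arrays of a group came from different animals. The Y-linked gene Eif2s3y was absent from WT T replicate 1 (log2 intensity 4.31; 8.60 and 8.35 on the other WT T arrays) and KO T replicate 3 (4.33; 8.49 and 8.26), so each T cell group held RNA of more than 1 animal. On KO iNKT replicates 1, 2 and 3 Eif2s3y stood at 7.87, 7.33 and 5.31, which does not settle whether they came from different animals. In the iNKT groups the errors and p-values may measure technical spread alone.

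The median signal per array was 88.3, 124 and 122 in WT stage 1-2 cells, 117, 105 and 109.7 in WT stage 3 cells, and 95.3, 92.5 and 92.2 in KO iNKT cells. It was 104, 93.1 and 109 in WT T cells and 93.8, 102 and 100.3 in KO T cells. Between 29.2% of probes (WT stage 3 replicate 2) and 40.8% (WT stage 1-2 replicate 3) were detected per array. Correlations between arrays of a group ranged from 0.942 in KO iNKT cells to 0.986 in WT T cells. The first principal component held 45.6% of the variance and placed the 6 T cell arrays at 32.0 to 41.5 and the 3 KO iNKT arrays at -46.3 to -33.3. The second held 22.6% and placed the 3 WT stage 3 arrays at -49.0 to -38.2, with every other array at 0.294 to 26.0. All 15 arrays entered 1 limma fit with a mean per group, 6838 genes were tested, and the 3 arrays per group limit the precision.

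Transcripts typical of granulocytes and other myeloid cells were present in the iNKT samples and differed between the groups. S100a8, a calcium-binding protein of granulocytes, had a mean log2 intensity of 13.2 in WT stage 1-2, 8.13 in WT stage 3 and 14.0 in KO iNKT cells, but 4.40 in WT T and 4.41 in KO T cells (n = 3 each). The lysozyme gene Lyz2 stood at 9.54, 6.19 and 11.2 in these iNKT groups and at 4.35 and 4.34 in the T cells. Siglech, a receptor of plasmacytoid dendritic cells, stood at 7.21, 5.16 and 9.10 in the iNKT groups. The mean log2 intensity of the 12 tested genes of the myeloid list lay at 7.71 to 8.18 on the WT stage 1-2 arrays, 5.33 to 6.31 on the WT stage 3 arrays, 8.47 to 9.45 on the KO iNKT arrays and 4.64 to 4.77 on the T cell arrays. These levels stand beside every comparison of iNKT groups given here.

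**Figure D1:**
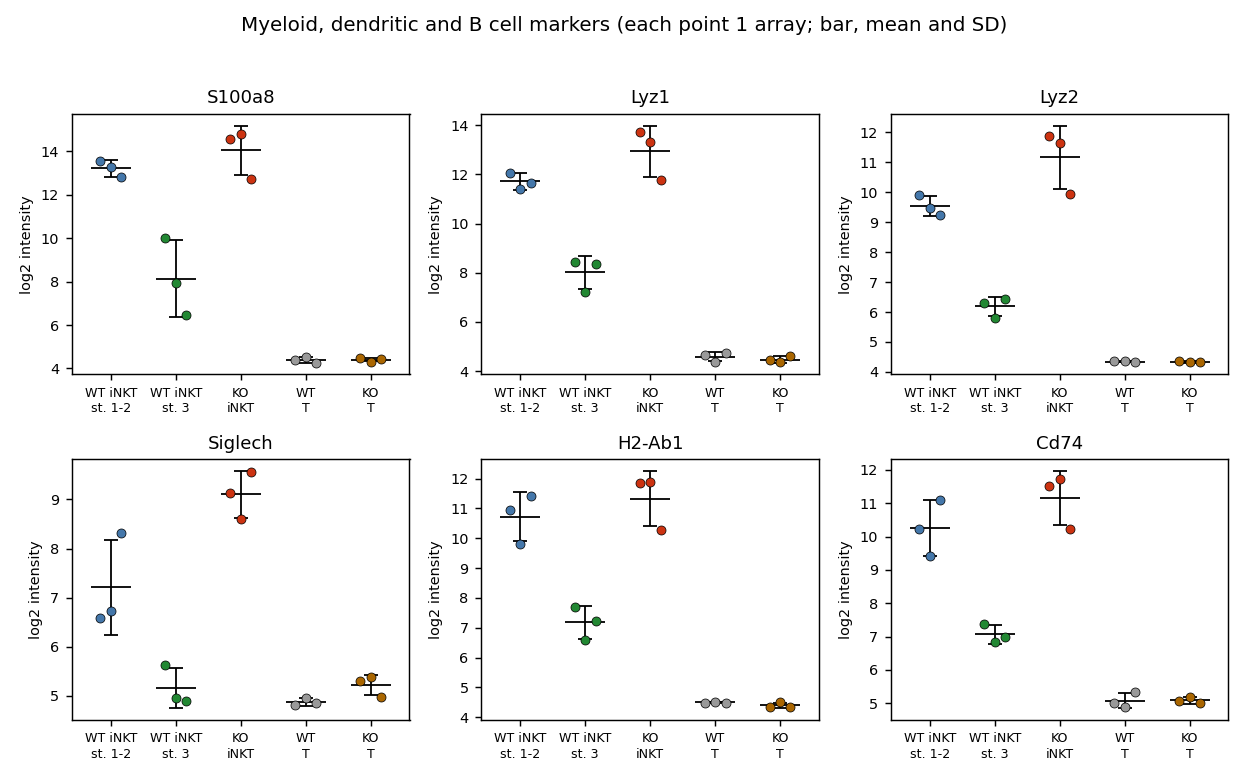
Log2 intensity of S100a8, Lyz1, Lyz2, Siglech, H2-Ab1 and Cd74 on each array (points) in the 5 groups, with the mean and SD of the 3 arrays as bars. S100a8 has a mean of 14.0 in KO iNKT, 13.2 in WT stage 1-2 and 8.13 in WT stage 3 cells, and of 4.40 and 4.41 in WT and KO T cells.

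The first comparison set Dicer KO iNKT cells against WT stage 1-2 iNKT cells. The KO cells were not split by stage, so that loss of Dicer is not separated from stage or from other cells in the samples. KO iNKT cells had more transcript of the receptors for TGF-β, a cytokine that restrains T cells and guides iNKT maturation: the type I receptor Tgfbr1 rose 3.26-fold (log2 change 1.71 ± 0.26, SE, n = 3 per group; adjusted p = 0.00193), the type II receptor Tgfbr2 rose by 1.18 ± 0.26 (adjusted p = 0.0206) and the co-receptor Tgfbr3 by 1.40 ± 0.34 (adjusted p = 0.032). Klf2, a transcription factor that drives exit from the thymus, rose 3.26-fold (1.71 ± 0.27, adjusted p = 0.00272). The costimulatory receptor Icos fell by 1.61 ± 0.25 (adjusted p = 0.00195), from a mean log2 intensity of 11.2 to 9.54. The Src-family kinase Blk fell by 1.83 ± 0.25 (adjusted p = 0.000826), from 8.43 to 6.59. Among 6838 genes 134 rose and 72 fell at adjusted p under 0.05, 1278 had an unadjusted p under 0.05, and 103 of the rising and 46 of the falling genes changed at least 2-fold.

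The 6 largest rises were those of Pdlim4, a PDZ and LIM domain protein (probe ILMN_2606162), the growth factor Igf2, Anxa1, Wnt10a, Cox6a2 and Smpdl3b. Pdlim4 rose 9.07-fold (3.18 ± 0.31, adjusted p = 5.45e-05), from a mean log2 intensity of 4.98 ± 0.69 (SD, n = 3) to 8.16 ± 0.57, and stood at 7.17 in WT T and 7.90 in KO T cells. Igf2 rose by 2.44 ± 0.56, Anxa1 by 2.34 ± 0.43, the Wnt ligand Wnt10a by 2.06 ± 0.26, Cox6a2, a subunit of cytochrome c oxidase, by 2.03 ± 0.35 and Smpdl3b by 2.01 ± 0.37. The 6 largest falls were those of Rnf208 (-2.0 ± 0.22, adjusted p = 1e-04), Fam20a (-1.91 ± 0.29), Blk, the water and glycerol channel Aqp3 (-1.71), the chemokine receptor Ccr6 (-1.67) and Icos. Of the 134 rising genes, 51 (38.1%) were detected on no T cell array, against 4.45% of all genes tested, and 26 of the 51 were also lower in WT stage 3 than in WT stage 1-2 cells. With KO replicate 1 left out, Igf2 (adjusted p up to 0.12 over the arrays left out), Smpdl3b (0.0531) and Ccr6 (0.0531) no longer passed; for Igf2 the same held without WT stage 1-2 replicate 2 or 3 or KO replicate 2.

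**Figure D2:**
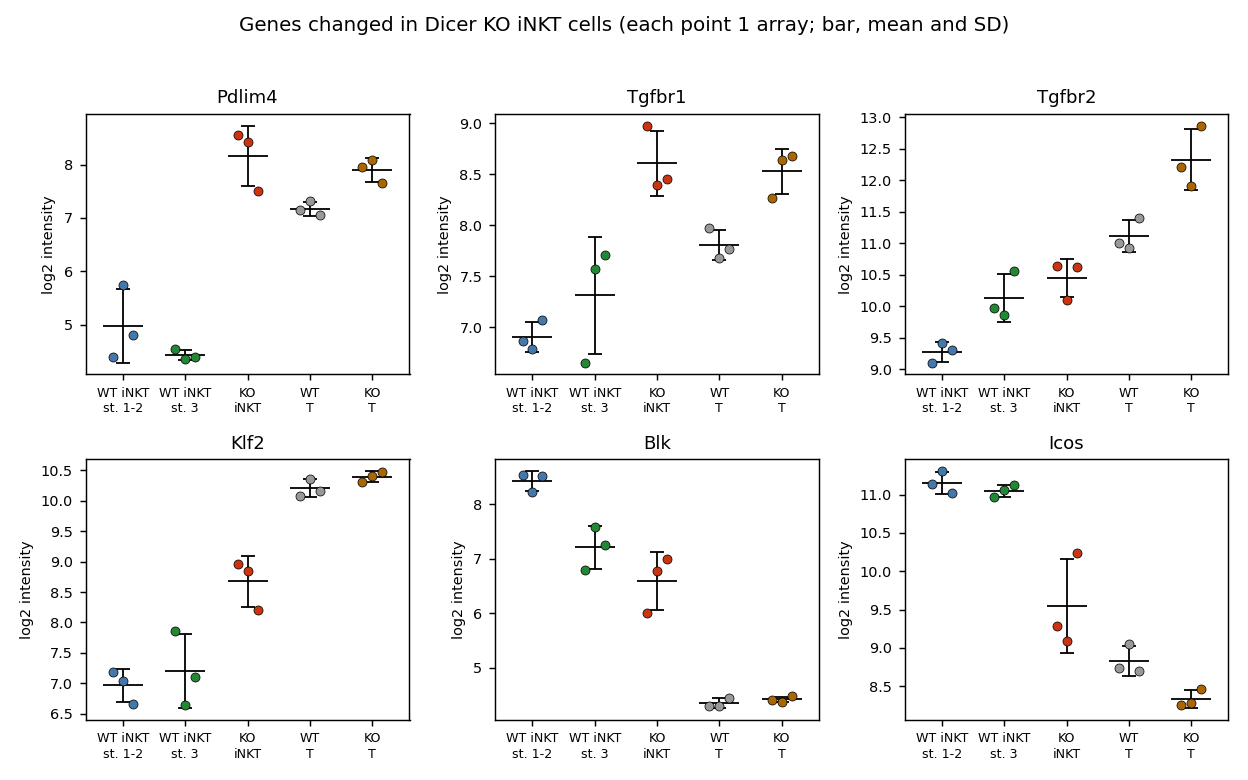
Log2 intensity of Pdlim4, Tgfbr1, Tgfbr2, Klf2, Blk and Icos on each array (points) in the 5 groups, with the mean and SD of the 3 arrays as bars. Pdlim4 has a mean of 8.16 in KO iNKT and 4.98 in WT stage 1-2 cells, and Icos of 9.54 and 11.2.

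Several fixed gene lists shifted in this comparison. Of 16 tested TGF-β pathway components 3 rose (Tgfbr1, Tgfbr2 and Tgfbr3) and none fell, 8 rose when adjusted over the list alone, and the list shifted up (median 0.32, adjusted p = 0.00242; adjusted p = 0.198 with an estimated correlation). Of 14 genes that TGF-β induces none changed (median 0.04, adjusted p = 0.761). Of 17 genes of naive T cells and thymic exit 2 rose, Klf2 and Igfbp4 (1.14 ± 0.21), with 6 adjusted over the list alone (median 0.66, adjusted p = 6.28e-05; adjusted p = 0.119 with an estimated correlation). The type 17 list, named after iNKT and T cells that make IL-17, fell: 4 of 14 genes, Blk, Aqp3, Ccr6 and the IL-17 receptor subunit Il17re (-1.29), or 5 adjusted over the list alone (median -0.39, adjusted p = 0.0217; adjusted p = 0.198 with an estimated correlation). Immediate early and heat shock genes rose, 3 of 19 and 5 adjusted over the list alone: the activation marker Cd69 (1.72 ± 0.24), Zfp36, which promotes decay of cytokine mRNAs (1.20), and Atf3 (1.01), with a list median of 0.48 (adjusted p = 0.0013; adjusted p = 0.162 with an estimated correlation). Of 30 type I interferon genes none changed, also adjusted over the list alone, while the list shifted up (median 0.28, adjusted p = 0.0217; adjusted p = 0.546 with an estimated correlation).

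Lists of other cells shifted in the same comparison. Of 12 myeloid genes 3 rose, Siglech (1.89), Lyz2 (1.62) and Ly86 (1.53), or 8 adjusted over the list alone (median 1.14, adjusted p = 4.95e-07; adjusted p = 0.159 with an estimated correlation). Of 9 genes of immature double-positive thymocytes Aqp11 rose (0.95), with 4 adjusted over the list alone (median 0.74, adjusted p = 0.0217; adjusted p = 0.162 with an estimated correlation). The B cell list, which includes the MHC class II genes H2-Aa, H2-Ab1 and Cd74, shifted up with none of 7 genes called (median 0.69, adjusted p = 0.0301; adjusted p = 0.563 with an estimated correlation). Of 3 γδ T cell genes Blk and Il17re fell, also adjusted over the list alone; both are also in the type 17 list (median -1.29, adjusted p = 0.000262; adjusted p = 0.159 with an estimated correlation).

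Among lists that did not shift, single genes changed. Il4, the cytokine of early iNKT cells, fell by 1.46 and Icos with it, as 2 of 16 genes of the early and type 2 list (adjusted p of the list = 0.919). The chemokine receptor Cxcr6 fell by 1.38, as 1 of 18 type 1 effector genes (list 0.972), and Bcl2a1d, a relative of Bcl2, fell by 1.61, as 1 of 10 survival genes (list 0.972), while Bcl2 itself had a change of 0.97 (adjusted p = 0.0721). Cd247, the ζ chain of the T cell receptor, fell by 1.44, whereas Cd69 and the phosphatase Dusp6 (1.08) rose, in 28 T cell receptor signalling genes (list median -0.18, 0.0906). The replication clamp Pcna rose by 1.38, as 1 of 36 cell cycle genes (list median -0.16, 0.139). Tgfbr2 and Dusp6 rose among 21 published microRNA targets (list median 0.09, 0.139), and Prkra, a Dicer partner, rose by 1.07 among 14 small RNA pathway genes (list 0.37). None of 15 NK receptors changed, with 4 rising and 2 falling adjusted over the list alone (list 0.868), and none of 29 ribosomal protein genes did (list median -0.17, 0.0578). The Dicer1 probe itself did not differ (0.08, adjusted p = 0.906); whether it lies in the deleted part is unknown.

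The count of 206 genes depended on single arrays. It was 71 without KO replicate 1, 130 without KO replicate 2 and 461 without KO replicate 3, and 90 and 325 without WT stage 1-2 replicate 2 and 3. Of 36 named genes that passed, 16 passed with each array left out in turn, among them Pdlim4, Tgfbr1, Klf2, Igfbp4, Cd69, Zfp36, Blk, Il17re and Icos. Without KO replicate 1 the calls were lost of Tgfbr2 (adjusted p up to 0.0986), Tgfbr3 (0.155), Bcl2a1d (0.151), Cxcr6 (0.0625), Il4 (0.151), Cd247 (0.0659), Dusp6 (0.142), Pcna (0.133), Prkra (0.111), Aqp11 (0.166), Lyz2 (0.12) and Ly86 (0.188). The same 12 calls were lost without WT stage 1-2 replicate 2, as were those of Atf3 (0.0563) and Siglech (0.0517). Without WT stage 1-2 replicate 1 those of Tgfbr2, Tgfbr3, Il4, Dusp6, Pcna, Prkra, Aqp11 and Ly86 were lost, and without KO replicate 2 those of Tgfbr3, Bcl2a1d, Il4, Pcna, Prkra, Aqp11, Lyz2 and Ly86. That of Dusp6 was also lost without KO replicate 3 and that of Aqp11 without WT stage 1-2 replicate 3. Median scaling in place of quantile normalization left 6 genes, among them Tgfbr1 (1.53), Klf2 (1.57), Cd69 (1.68) and Icos (-1.60), and moved the median of all genes to 0.20; Pdlim4 then had a change of 2.45 (adjusted p = 0.0508; 2.44e-07 to 0.0527 over 12 settings), and the median of the type 17 list stood at 0.01, or -0.20 relative to all genes. A fit of the compared groups alone left 14 genes, array weights gave 553, and the mean of both WT stages as reference gave 1215.

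The second comparison set KO iNKT cells against the mature WT stage 3 cells, because KO cells were sorted without a split by stage. KO iNKT cells had far less transcript of NK receptors and of type 1 effector genes, those of killing and interferon-γ responses. The NK receptor gene Klre1 was at least 38.1-fold lower (adjusted p = 1.57e-10) and the Ly49 receptor Klra7 at least 18.9-fold lower (1.3e-10). Tbx21, the transcription factor T-bet, fell by 2.47 ± 0.21 (adjusted p = 2.86e-07), the death ligand Fasl fell by 4.38 ± 0.30 (1.94e-08) and the survival gene Bcl2 fell by 2.15 ± 0.28 (2.49e-05). The cell cycle list was higher, with the DNA methylation factor Uhrf1 up by 2.13 (3.71e-06), but not with an estimated correlation (adjusted p = 0.151 with an estimated correlation). The 6 largest rises were those of the granulocyte genes S100a9 (6.70 ± 0.68, 104-fold; adjusted p = 1.48e-06), Ltf (6.68), Camp (6.31), S100a8 (5.91 ± 0.62) and Lcn2 (5.78), and of Alox5ap (6.29 ± 0.32), which acts in leukotriene synthesis in many leukocytes. Among 6838 genes 1091 rose and 956 fell.

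By list, 12 of 15 NK receptors fell and 1 rose, with 12 and 2 adjusted over the list alone (median -2.58, adjusted p = 5e-09, 0.0216 with an estimated correlation); further falls were those of Klra10 (-4.65), Klra1 (-4.46) and Klrd1 (-3.27). Of 18 type 1 effector genes 13 fell and 2 rose, with 14 and 2 adjusted over the list alone (median -2.26, adjusted p = 1.8e-07, 0.0201 with an estimated correlation). The chemokine Xcl1 fell by 4.02, while Ccl4, another chemokine, rose by 3.25. Of 28 T cell receptor signalling genes 17 fell and 2 rose, with 18 and 2 adjusted over the list alone, among them Ptpn22 (-1.96), the kinases Zap70 (-1.72) and Fyn (-1.59) (median -0.89, adjusted p = 3.36e-06; adjusted p = 0.132 with an estimated correlation). Of 10 survival genes 4 fell and 1 rose, including Bcl2a1d (-2.78) and Bcl2a1c (-1.90) (median -0.30, adjusted p = 0.0356; adjusted p = 0.132 with an estimated correlation). Of 36 cell cycle genes 22 rose and 1 fell, with 23 and 1 adjusted over the list alone, among them Stmn1 (2.42) and E2f2 (1.97) (median 1.33, adjusted p = 6.07e-09; adjusted p = 0.151 with an estimated correlation). Of 17 naive T cell genes 7 rose and 1 fell, with 7 and 3 adjusted over the list alone (median 0.37, adjusted p = 0.0189, 0.132 with an estimated correlation). The largest rises named from this list were those of Igfbp4 (5.46, adjusted p = 1.79e-11), Ly6d (5.10) and Cd8b1 (3.36). Over 11 settings the adjusted p in limma reached 0.0733 for Igfbp4, 0.972 for Ly6d and 0.956 for Cd8b1. A share from other cells in the rise of Ly6d was not tested, so it does not by itself show a naive T cell programme in KO iNKT cells.

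Markers of other cells moved with these groups. All 12 myeloid genes rose, also adjusted over the list alone, with Lyz2 at 4.97, Lyz1 at 4.92 and Siglech at 3.95 (median 3.73, adjusted p = 9.82e-11; adjusted p = 0.0509 with an estimated correlation). All 7 B cell genes rose, with H2-Ab1 at 4.15, H2-Aa at 4.14 and Cd74 at 4.09 (median 4.06, adjusted p = 5.68e-08; adjusted p = 0.132 with an estimated correlation). Of 9 double-positive thymocyte genes 4 rose and 1 fell, also adjusted over the list alone; Dntt, the enzyme that adds bases at V(D)J joints, was at least 5.06-fold higher and Arpp21 at least 3.62-fold higher (median 0.93, adjusted p = 0.0294; adjusted p = 0.132 with an estimated correlation). Of the 1091 rising genes 203 (18.6%) were detected on no T cell array. The count of changed genes was 1450 to 2139 with 1 array left out and 818 with median scaling. Dicer1 fell by 0.84 (adjusted p = 0.0167), a call lost without WT stage 3 replicate 1 or 3 or KO replicate 2 (adjusted p up to 0.0837).

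Because KO iNKT cells were an unsplit pool, genes beyond both WT groups in one direction are those that no mixture of these groups as sorted would give. The stage 1-2 group is itself a pool, and another ratio of stage 1 to stage 2 in KO cells was not tested. In KO iNKT cells 113 genes were higher and 50 lower than in both WT stages, 79.1% of the 206 genes of the first comparison. In 50 simulations in which no group differed from another the highest count was 1, and independent lists would share 21.4 rising and 10.1 falling genes. The data hold a stage difference, which the simulations lack, and both tests use the same KO arrays. These counts therefore do not show how many genes chance would give here. The rising genes with the largest smaller change were again Pdlim4 (at least 8.62-fold against stage 3), Igf2 (3.01), Anxa1 (at least 4.41-fold), Wnt10a (at least 3.24-fold), Cox6a2 (5.63) and Smpdl3b (3.19). The falling ones were Bcl2a1d (-2.78 against stage 3), Icos (-1.51), the repressor Snai3 (-1.54), Cd247 (-1.61), the ubiquitin ligase Rnf114 (-2.0) and the translation elongation factor Eef2 (-1.71). Of the 113 genes 49 (43.4%) were detected on no T cell array. The count of 163 genes was 103 without WT stage 1-2 replicate 1, 66 without replicate 2 and 255 without replicate 3 of that group, and 58, 98 and 389 without KO replicate 1, 2 and 3. In the first comparison, the calls of Eef2 (adjusted p up to 0.121, without WT stage 1-2 replicate 1 or 2 or KO replicate 1 or 2) and Snai3 (0.05, without WT stage 1-2 replicate 2) were lost. Median scaling gave 5 genes, a fit of the compared groups alone 32 and array weights 391. With the mean of the myeloid list as a covariate, a setting chosen after the data were seen, 1 gene remained, as standard errors rose 1.54 times in the first and 3.75 times in the second comparison and the median size of the called changes went from 1.13 to 0.96 and from 1.03 to 0.76. The changes against stage 3 turned to -2.96 for Igf2, -1.07 for Anxa1, 0.60 for Icos, 0.63 for Snai3 and 0.66 for Eef2. They had the same sign for Pdlim4 (2.67), Wnt10a (0.39), Cox6a2 (4.89), Smpdl3b (2.65), Bcl2a1d (-0.63), Cd247 (-0.64) and Rnf114 (-0.50).

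On an axis from WT stage 1-2 (position 0) to WT stage 3 (position 1), the KO iNKT arrays lay at the stage 1-2 end. Their mean position was -0.0869 ± 0.142 (SD, n = 3), with single arrays from -0.194 to 0.0741. Held-out WT stage 1-2 arrays lay at 0.0773 ± 0.0807 and held-out stage 3 arrays at 0.944 ± 0.116. The axis rested on 295 to 457 genes, and with 1 array left out the KO mean ranged from -0.171 to -0.0341. No test was run on the positions, and the axis genes include granulocyte genes that fall from stage 1-2 to stage 3.

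**Figure D3:**
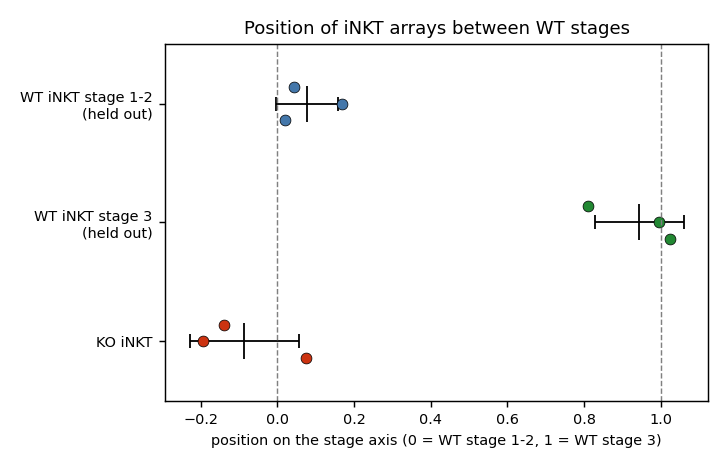
Position of each KO iNKT array and of each held-out WT iNKT array (points) on the axis from WT stage 1-2 (0) to WT stage 3 (1), both marked by dashed lines. The KO arrays lie between -0.194 and 0.0741, and the stage 3 arrays between 0.811 and 1.02.

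The comparison of KO with WT T cells asked what loss of Dicer changes in conventional thymic T cells. Here 8 genes rose and 2 fell among 6838, and 647 had an unadjusted p under 0.05. The histone gene H2bc4 rose 4.58-fold (2.19 ± 0.33, n = 3 per group, adjusted p = 0.00975), from a mean log2 intensity of 5.39 to 7.58. Socs3, an inhibitor of cytokine signalling, rose 3.00-fold (1.59 ± 0.23, adjusted p = 0.00781) and the kinase Tec by 1.49 ± 0.28 (0.0329). Gramd3 (1.76 ± 0.29), Man2a1, an enzyme of N-glycan processing (1.33), Fam91a1 (1.31), Iqgap2 (1.26) and the NK receptor Klrd1 (1.22) rose too; Iqgap2 was outside the rule for named genes and is added to complete the count. Lgals3, the lectin galectin-3, fell by 1.80 ± 0.26 (0.00781), from 7.84 to 6.05, and Plac8 by 1.47 ± 0.26 (0.0243).

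Gene lists in T cells shifted without called members. The 16 TGF-β pathway components shifted up, with 2 genes adjusted over the list alone (median 0.23, adjusted p = 0.00997; adjusted p = 0.585 with an estimated correlation). Tgfbr2 had a change of 1.22 (adjusted p = 0.0677) and Tgfbr1 of 0.72 (0.402). The 17 naive T cell genes shifted up, with 1 adjusted over the list alone, Igfbp4 at 0.93 (0.0757) (median 0.27, adjusted p = 0.00997; adjusted p = 0.585 with an estimated correlation). The 21 microRNA targets shifted up, with 1 adjusted over the list alone (median 0.19, adjusted p = 0.0311; adjusted p = 0.623 with an estimated correlation), and the 29 ribosomal protein genes shifted down, with none adjusted over the list alone (median -0.19, adjusted p = 0.00997; adjusted p = 0.623 with an estimated correlation). The 12 myeloid genes had a median change of 0.02. Dicer1 had a change of -0.06 (adjusted p = 0.977), and the argonaute gene Ago2 of 0.91 (0.0677).

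Without WT T replicate 1 none of the genes passed in limma (448 at an unadjusted p under 0.05), 1 did without WT T replicate 2, KO T replicate 2 or KO T replicate 3, and 4 without WT T replicate 3. The calls of Tec (adjusted p up to 0.261), Klrd1 (0.186) and Plac8 (0.189) were lost without any 1 of the 6 T cell arrays. Without WT T replicate 1 those of H2bc4 (0.0965), Gramd3 (0.16), Socs3 (0.0607), Man2a1 (0.129), Fam91a1 (0.2) and Lgals3 (0.0607) were lost as well. Without WT T replicate 2 the same held but for Lgals3, and without WT T replicate 3 H2bc4 and Man2a1 were lost. Without KO T replicate 2 all of these but Socs3, and without KO T replicate 3 all but H2bc4, were lost. Other settings gave more genes, 28 with quantile normalization without background correction and 144 with array weights, whereas median scaling gave 2. The rise of Tgfbr2 passed with quantile normalization without background correction (1.20, adjusted p = 0.0276) and with array weights (1.10, adjusted p = 0.0128; 0.0128 to 0.999 over 11 settings).

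The KO effects in iNKT cells (against WT stage 1-2) and in T cells were then tested against each other. They differed for 12 genes, 9 with a more positive and 3 with a more negative change in iNKT cells, and 590 had an unadjusted p under 0.05. Pdlim4 changed by 3.18 in iNKT and 0.72 in T cells, a difference of 2.46 ± 0.43 (adjusted p = 0.0342). Wnt10a changed by 2.06 and -0.02, a difference of 2.08. Plac8 had a change of 0.55 in iNKT cells and fell by 1.47 in T cells, a difference of 2.02. Blk changed by -1.83 and 0.07 (difference -1.90), Rnf208 by -2.0 and -0.33 (-1.67) and Fam20a by -1.91 and 0.21 (-2.12, adjusted p = 0.0408). The other called differences were those of Klra17 (2.11) and Pld4 (2.00), both known from plasmacytoid dendritic cells, and of Tns4 (2.07), Klk1 (1.86), Klk1b5 (1.91) and Gm12253 (1.92). Of the 12 genes only Pdlim4 and Plac8 were detected on all 6 T cell arrays, and 6, Blk among them, on none. Of the 10 others Blk, Rnf208 and Fam20a fell in iNKT cells, and a like fall in T cells could not be measured. The rest rose in iNKT cells. A rise in T cells could have been measured for them, and their changes there lay between -0.18 (Klra17) and 0.06 (Klk1). Whether their rises came from iNKT cells or from other cells in the iNKT samples was not tested. The myeloid list (median 1.18, adjusted p = 1.88e-05; adjusted p = 0.284 with an estimated correlation) and the B cell list (0.79, adjusted p = 0.0148; adjusted p = 0.538 with an estimated correlation) shifted too. Their medians were close to those in iNKT cells alone (1.14 and 0.69), and 1 of 12 and 0 of 7 genes were detected on all T cell arrays. The difference was not called for Tgfbr1, Tgfbr2, Klf2 or Icos. Across all genes the changes in iNKT and T cells had a Pearson r of 0.262 and a Spearman rho of 0.280, where genes are not independent replicates. Of the 134 genes that rose in KO iNKT cells 92 had a positive change in T cells, against 50.1% of all genes (median 0.11, camera p = 2.59e-08 and 0.0362 with an estimated correlation), and 45 of the 72 falling genes had a negative one (median -0.12, p = 0.00306; p = 0.0912 with an estimated correlation). However, 51 of the rising and 5 of the falling genes were detected on no T cell array, and the sign of their T cell change says little. Fam91a1 was the 1 gene that rose in both cell types (1.27 in iNKT cells), with 0.157 expected from independent lists. The 12 calls were few without 1 array: 3 without WT stage 1-2 replicate 1, 1 without replicate 2, 3 without KO iNKT replicate 1, and 0 in limma without KO iNKT replicate 2 or any 1 of the 6 T cell arrays (452 to 620 genes at an unadjusted p under 0.05); they were 38 without WT stage 1-2 replicate 3 and 118 without KO iNKT replicate 3. Every named call was lost at least once (adjusted p up to 0.144), and median scaling gave 0 (239 at an unadjusted p under 0.05).

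WT stage 3 was set against WT stage 1-2 to ask what changes as iNKT cells mature. Mature cells gained NK receptors, type 1 effector genes and Bcl2. They lost cell cycle genes (adjusted p = 8.78e-14; adjusted p = 0.0735 with an estimated correlation). Klra7 was at least 17.9-fold higher (adjusted p = 5.5e-10), Klre1 rose by 5.57 ± 0.26 (4.38e-10), from a group in which 1 of 3 arrays detected it, and Fasl rose 13.9-fold (3.80 ± 0.30, 2.17e-07). Tbx21 rose 5.04-fold (2.33 ± 0.21, adjusted p = 1.21e-06) and Bcl2 8.65-fold (3.11 ± 0.28, 1.21e-06). Uhrf1 fell by 2.45 ± 0.23 (2.04e-06). The chemokine Xcl1 rose by 4.61, Klra10 by 4.07 and Klrd1 by 3.85. The 6 largest falls were those of the granulocyte genes S100a9 (-5.32 ± 0.68, adjusted p = 3.64e-05), Ltf (-5.30), S100a8 (-5.09), Camp (-4.84) and Lcn2 (-4.49), and of Alox5ap (-4.85). Among 6838 genes 623 rose and 754 fell.

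**Figure D4:**
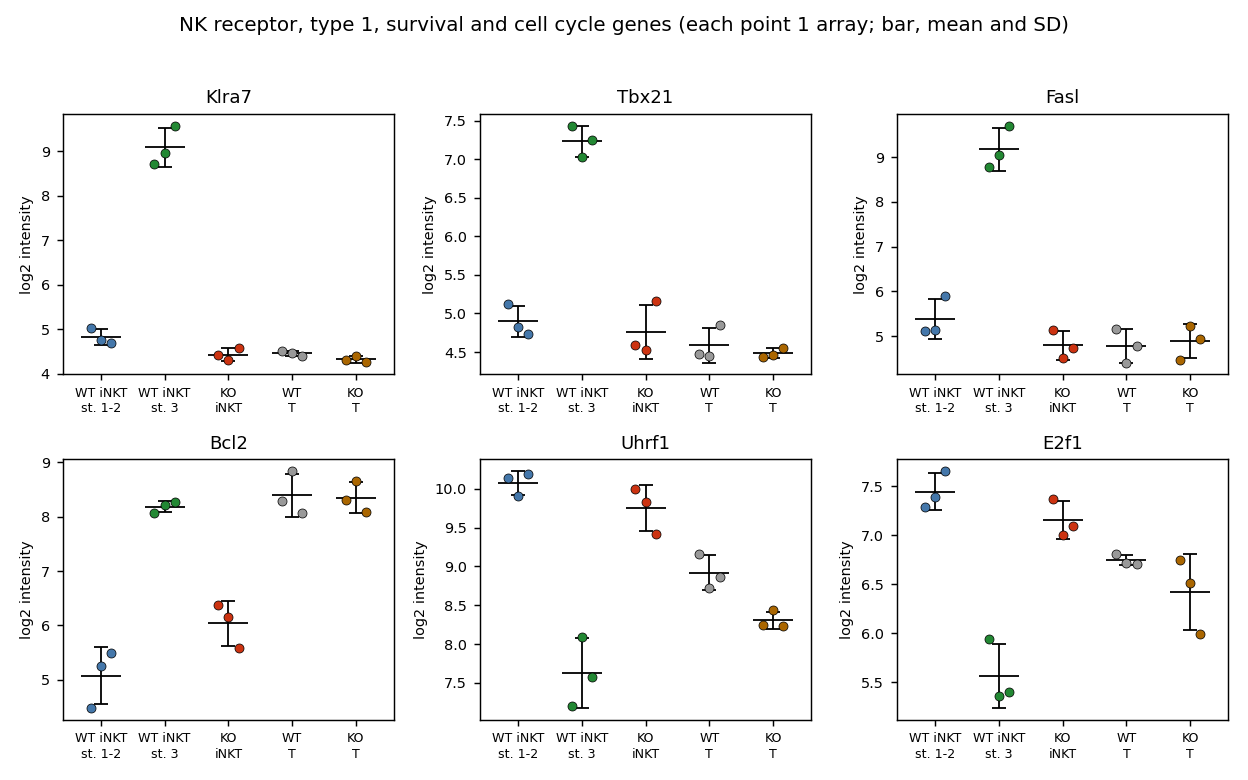
Log2 intensity of Klra7, Tbx21, Fasl, Bcl2, Uhrf1 and E2f1 on each array (points) in the 5 groups, with the mean and SD of the 3 arrays as bars. From WT stage 1-2 to stage 3, Tbx21 rose by 2.33 and Bcl2 by 3.11, and E2f1 fell by 1.88.

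Of 15 NK receptors 11 rose and 1 fell, with 12 and 1 adjusted over the list alone (median 2.36, adjusted p = 8.78e-14, 0.00446 with an estimated correlation), and of 18 type 1 effector genes 13 rose and 2 fell, also adjusted over the list alone (median 2.04, adjusted p = 3.26e-09, 0.00446 with an estimated correlation). Of 36 cell cycle genes 24 fell and none rose, with 29 and 1 adjusted over the list alone, among them E2f2 (-2.13) and E2f1 (-1.88) (median -1.31, adjusted p = 8.78e-14; adjusted p = 0.0735 with an estimated correlation). Of 10 survival genes 5 rose and 1 fell, with 6 and 1 adjusted over the list alone, including the kinase Pim1 (1.16) (median 0.70, adjusted p = 0.00688; adjusted p = 0.0735 with an estimated correlation). Of 28 T cell receptor signalling genes 12 rose and none fell, with 15 and 1 adjusted over the list alone, among them Malt1 (1.86), Ptpn22 (1.62) and Nr4a3 (1.48) (median 0.58, adjusted p = 8.25e-06; adjusted p = 0.0735 with an estimated correlation). Of 14 TGF-β induced genes 7 rose and 2 fell, with 8 and 2 adjusted over the list alone, among them Junb (2.07), Bhlhe40 (2.04) and the proapoptotic Bcl2l11 (1.45) (median 0.85, adjusted p = 0.019; adjusted p = 0.109 with an estimated correlation). Of 21 microRNA targets 11 rose and 2 fell, also adjusted over the list alone, with Tbx21, Ptpn22 and the interferon-γ receptor Ifngr1 (2.65) among them (median 0.83, adjusted p = 0.000257; adjusted p = 0.0735 with an estimated correlation).

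Early and type 2 genes fell, 6 of 16 with 1 rising, or 8 and 1 adjusted over the list alone, among them Plac8 (-3.00), the chemokine receptor Ccr7 (-2.15) and the IL-25 receptor Il17rb (-2.14) (median -0.63, adjusted p = 0.00732; adjusted p = 0.0735 with an estimated correlation). Of 14 type 17 genes 6 fell and 2 rose, with 8 and 2 adjusted over the list alone, including Ccr6 (-2.21) and Blk (-1.21) against Ltb (1.20) (median -0.77, adjusted p = 0.0444; adjusted p = 0.175 with an estimated correlation). Of 17 cytokine receptors 5 rose and 2 fell, with 6 and 3 adjusted over the list alone, led by Ifngr1, Il2rb (2.36), which binds IL-2 and IL-15, and Il18rap (2.07) (median 0.48, adjusted p = 0.0247; adjusted p = 0.0735 with an estimated correlation). Of 15 chemokine receptors and adhesion genes 6 rose and 2 fell, with 7 and 2 adjusted over the list alone, with Ccr8 up by 2.60 (median 0.65, adjusted p = 0.017; adjusted p = 0.0735 with an estimated correlation). Immediate early genes rose, 6 of 19 with 1 falling, or 9 and 1 adjusted over the list alone, with Dusp1 at 2.39 and Ier3 at -2.05 (median 0.22, adjusted p = 0.0214; adjusted p = 0.179 with an estimated correlation). Of 13 glycolysis genes 3 fell and 1 rose, with 6 and 1 adjusted over the list alone: Egln3 (-1.39), Pfkm (-0.79) and the glucose transporter Slc2a1 (0.93) (median -0.43, adjusted p = 0.0444; adjusted p = 0.149 with an estimated correlation). Dicer1 rose by 0.93 (adjusted p = 0.0143).

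Other-cell markers moved with the stages. Of 12 myeloid genes 9 fell, also adjusted over the list alone, with Lyz1 at -3.69 and Lyz2 at -3.36 (median -2.14, adjusted p = 3.81e-08; adjusted p = 0.0735 with an estimated correlation), and all 7 B cell genes fell, with H2-Ab1 at -3.54, H2-Aa at -3.23 and Cd74 at -3.19 (median -3.19, adjusted p = 2.06e-08; adjusted p = 0.0735 with an estimated correlation). All 3 γδ T cell genes fell, Blk, Cd163l1 (-1.14) and Il17re (-0.95) (median -1.14, adjusted p = 0.0143; adjusted p = 0.149 with an estimated correlation). Of 5 NK and innate lymphoid genes 3 rose, among them Klre1 and Klri2 (at least 1.72-fold), and the adaptor Tyrobp, which myeloid cells also express, fell by 2.43, with 4 and 1 adjusted over the list alone (median 1.34, adjusted p = 0.00688; adjusted p = 0.162 with an estimated correlation). Of the 754 falling genes 116 (15.4%) were detected on no T cell array. The count was 1005 to 1275 with 1 array left out, 496 with median scaling and 804 in a fit of both stages alone. Single calls were lost with an array left out: Cd163l1 without any of the 6 but WT stage 1-2 replicate 3 (adjusted p up to 0.121), Dicer1 without WT stage 1-2 replicate 1 or stage 3 replicate 3 (0.0714), Pfkm without replicate 3 of either stage (0.0701), and Bcl2a1c (1.04) without WT stage 1-2 replicate 3 (0.0548). The type 17 call was lost with quantile normalization without background correction.

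The last comparison, of the mean of both WT iNKT stages (6 arrays) with WT T cells (3 arrays), asked what sets iNKT cells apart. WT iNKT cells had more transcript of type 1, NK and type 17 genes and less of naive T cell genes. The chemokine Ccl4 rose by 3.73 (adjusted p = 3.29e-09), the IL-18 receptor Il18r1 by 2.81 and Blk at least 7.29-fold, whereas Cd8b1, a chain of the CD8 coreceptor, fell by 4.48 ± 0.27 (22.3-fold lower; 3.29e-09) and Igfbp4 by 3.72 ± 0.18 (9.88e-10). Unlike most type 1 genes, Ccl4 was higher in KO iNKT than in WT stage 3 cells (3.25), and a share from other cells in its rise was not tested. The 6 largest rises included S100a8 (at least 52.8-fold), Lyz1 (at least 30.1-fold), S100a9 (at least 20.3-fold), Fcer1g (at least 22.4-fold), H2-Ab1 and the transcription factor Cebpb (4.50 ± 0.26). The other large falls were those of Ddit4 (-4.52 ± 0.30), an inhibitor of mTOR, Nsg2 (-3.76), and Tdrp (-4.18) and Gpr83 (-3.90), each detected on 1 of the 6 WT iNKT arrays. Among 6838 genes 759 rose and 855 fell.

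Of 18 type 1 effector genes 13 rose and none fell, with 15 adjusted over the list alone (median 1.96, adjusted p = 2.42e-11, 0.0031 with an estimated correlation), of 15 NK receptors 13 rose, with 14 adjusted over the list alone (median 1.62, adjusted p = 6.29e-12, 0.00473), and of 14 type 17 genes 9 rose and 2 fell, also adjusted over the list alone (median 1.26, adjusted p = 1.58e-05, 0.0217). Of 17 naive T cell genes 13 fell and 1 rose, also adjusted over the list alone, with the actin crosslinker Actn1 at -3.50 (median -1.53, adjusted p = 1.21e-09, 0.00473 with an estimated correlation). Of 14 TGF-β induced genes 8 rose and 1 fell, with 9 and 1 adjusted over the list alone, led by Bhlhe40 (3.90), Gadd45b (at least 8.13-fold) and Junb (2.83) (median 0.89, adjusted p = 3.05e-05, 0.0217). Of 13 glycolysis genes 8 rose and 2 fell, also adjusted over the list alone, with the hexokinase Hk2 at 2.48 and Tpi1 at 1.88 (median 0.81, adjusted p = 0.000523, 0.0308), and of 19 immediate early genes 10 rose and 2 fell, with 12 and 3 adjusted over the list alone, with Dusp1 at 2.32 (median 0.98, adjusted p = 1.58e-05, 0.0362). Of 30 type I interferon genes 16 fell and 3 rose, with 18 and 3 adjusted over the list alone, among them Oas2 (-1.87) and Igtp (-1.60) (median -0.74, adjusted p = 3.05e-05; adjusted p = 0.0991 with an estimated correlation). Of 17 cytokine receptors 6 rose and 3 fell, with 7 and 3 adjusted over the list alone, with Il17rb at 3.05 (median 0.29, adjusted p = 0.0358; adjusted p = 0.0701 with an estimated correlation).

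Among other-cell lists 8 of 12 myeloid genes rose, with 8 rising and 1 falling adjusted over the list alone (median 1.35, adjusted p = 2.59e-06; adjusted p = 0.0701 with an estimated correlation), and 6 of 7 B cell genes rose, also adjusted over the list alone, with H2-Eb1 at least 11.2-fold higher (median 3.16, adjusted p = 2.73e-06; adjusted p = 0.0991 with an estimated correlation). All 3 γδ T cell genes rose, with Cd163l1 at 2.80 (median 2.80, adjusted p = 1.18e-05, 0.0302), and 4 of 5 NK and innate lymphoid genes did, or 5 adjusted over the list alone, with Klre1 at least 5.10-fold and Tyrobp at least 3.92-fold higher (median 2.53, adjusted p = 1.14e-05, 0.0485). Of the 759 rising genes 132 (17.4%) were detected on no T cell array. Dicer1 had a change of 0.27 (adjusted p = 0.395). The count was 1106 to 1661 with 1 array left out and 916 with median scaling, and all 39 named genes passed with each array left out (adjusted p up to 0.000955). With WT stage 1-2 alone as the iNKT group Klre1 had a change of -0.01 (adjusted p = 0.979; 2.02e-10 to 0.979 over 13 settings).

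The comparisons that involve iNKT cells were repeated with the mean of the myeloid list as a covariate, a setting chosen after the data were seen. KO iNKT cells then differed from WT stage 1-2 cells in 1 gene and from WT stage 3 cells in 2, WT stage 3 from stage 1-2 cells in 24 and WT iNKT from WT T cells in 161 genes. The covariate follows the groups, so that the median standard error rose 1.54, 3.75, 2.62 and 2.91 times in these comparisons. In KO iNKT against WT stage 1-2 cells Pdlim4 then had a change of 2.83 (adjusted p = 0.0527) and Tgfbr1 of 2.00 (0.106), while that of Klf2 shrank to 0.81 (0.411) and that of Icos to -0.93 (0.344); none of the 4 passed. Of the genes called without the covariate 205 of 206 had the same sign in this comparison, 1438 of 2047 against stage 3, 1146 of 1377 for stage 3 against stage 1-2 and 1488 of 1614 for WT iNKT against WT T cells. Against stage 3 the changes of S100a9, Ltf, Camp, S100a8, Lcn2, Dntt, Arpp21, Cd74, H2-Ab1, H2-Aa, Igf2 and Anxa1 turned negative and those of Zap70, Icos, Snai3 and Eef2 positive. S100a8 and S100a9 belong to the myeloid list whose mean is the covariate, so the loss of their differences follows from the setting itself. Alox5ap stood at 2.89 (adjusted p = 0.478; 2.35e-12 to 0.478 over 11 settings).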

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

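All 3 tests of array background, the share from abundant T cell genes, the comparison of the spread between arrays and the comparison of effect sizes were chosen only after the results were seen. The difference between KO and WT iNKT cells (stage 1-2) was unlike that in T cells for 12 genes by a test of the difference. Only Pdlim4 and Plac8 were detected on all 6 T cell arrays; 6 of the 12 (Blk and Klra17 among them) were detected on none and 4 on 1 or 2. Of these 10 genes Blk, Rnf208 and Fam20a fell in iNKT cells, and a like fall in T cells could not be measured. The rest rose in iNKT cells, and a rise in T cells could have been measured but was not seen. RNA of other cells in the iNKT samples could also give such rises, so these genes do not show that the cell types respond differently. The difference was 2.46 for Pdlim4, 2.11 for Klra17 (Ly49Q, known from plasmacytoid dendritic cells), 2.08 for Wnt10a, 2.07 for Tns4 and 2.02 for Plac8, and -2.12 for Fam20a, -1.90 for Blk and -1.67 for Rnf208. By list the median difference was -0.52 for type 17 genes (adjusted p = 0.00601; adjusted p = 0.272 with an estimated correlation) and -0.35 for T cell receptor signalling (adjusted p = 0.0118; adjusted p = 0.538 with an estimated correlation). It was 0.79 for B cell genes (adjusted p = 0.0148; adjusted p = 0.538 with an estimated correlation), 1.18 for myeloid genes (adjusted p = 1.88e-05; adjusted p = 0.284 with an estimated correlation) and -1.33 for γδ T cell genes (adjusted p = 5.22e-05; adjusted p = 0.192 with an estimated correlation). Few genes of the B cell, myeloid, γδ T cell and type 17 lists were detected on all 6 T cell arrays (0 of 7, 1 of 12, 1 of 3 and 4 of 14). For γδ T cell and type 17 genes not detected there, a fall in T cells could not be measured. A rise of B cell and myeloid genes could have been, but these lists name markers of other cells. So none of these lists shows that the cell types respond differently. Of the T cell receptor signalling genes 25 of 28 were detected on all 6. With 1 array left out the count was 0 in limma without KO iNKT replicate 2 (577 genes at an unadjusted p under 0.05). It was also 0 without any 1 of the 6 T cell arrays (452 to 620 genes), and it was 118 without KO iNKT replicate 3. Of 100 drawn splits of the arrays 2 gave as many genes, the real one included, a share under 0.05. The other split gave 17 genes, more than the real 12, so chance is not excluded for these calls.

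Granulocyte and plasmacytoid dendritic cell transcripts, such as S100a8 (mean log2 intensity 14.0 in KO iNKT and 13.2 in WT stage 1-2 cells), were abundant in iNKT arrays (S100a8 stood at 4.40 in WT T cells). The values argue against array background: the 12 genes of the myeloid list lay 3.97 higher in KO iNKT than in KO T cells at the median (interval over genes 1.49 to 7.64; 11 higher, Ctss at -0.09), while the KO iNKT arrays were no brighter (median signal 92.5 and 100.3); the earlier tests, which asked that no gene be lower and that at most 10% of detections fall on T cell arrays, did not exclude it, the second with 27.8% (up to 50% on an array; 100% on WT stage 1-2 and KO iNKT arrays) from Elane, Mmp9 and Prtn3 near the floor. RNA from other cells in the sorted samples is a candidate explanation: 6 granulocyte genes not looked at before deviated together from their group means over the 9 iNKT arrays (median pairwise correlation 0.911, against 0.289 at the 95th percentile of random lists), and 8 plasmacytoid genes had a median change of 0.77 between KO and WT stage 1-2 cells (7 above 0, camera p = 0.00812 with an estimated correlation). The sort for HSA low, TCRβ intermediate and CD1d tetramer positive cells selects against both cell types, but the purity of the sorted samples is not known. Of the 8 plasmacytoid genes 6 were also detected on at least 1 T cell array. Among the 8, Atp1b1 (change 1.31) stood higher in WT T (9.06) and KO T cells (9.48) than in KO iNKT cells (8.78). It also belongs to the gene set of the next paragraph. Pacsin1 (0.0043), Havcr1 (0.083) and Ptprf (-0.081) changed little. Expression of these genes by iNKT cells of a given stage or genotype also stays open and was not tested.

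A set of 20 genes that were higher in KO iNKT than in WT stage 1-2 cells was also high in WT T cells, among them Klf2, Tgfbr2, Igfbp4, Cd69 and Pdlim4. The values argue against the dim array WT stage 1-2 replicate 1 as the source of the pattern, because 18 of the 20 genes kept at least 0.75 of their log2 rise without it; 9 of them also kept an adjusted p under 0.05. They also argue against T cells in the KO iNKT samples as its source: the pattern needed 46.5%, 27.7% and 43.2% of KO T cell RNA on the 3 KO arrays, whereas 19 genes abundant in WT T cells implied up to 3.78% (upper ends of the intervals 8.49%, 9.42% and 3.94%). Genes detected on T cell arrays alone, which lie near the floor, implied 5.90%, 7.67% and 6.36% (upper ends 13.3%, 25.8% and 15.2%), so that a small share of T cells stays open. A change within KO iNKT cells, through loss of Dicer, may give the pattern and was not tested.

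Between KO and WT cells 10 genes differed in T cells and 206 in iNKT cells (against WT stage 1-2). Larger spread between the T cell arrays was not seen: the median SD within a group was 0.223 in KO T and 0.277 in KO iNKT arrays, and 0.185 in WT T and 0.284 in WT stage 1-2 arrays. A KO effect of the same size in both cell types stays open, since the mean squared log2 change less its error was 0.0584 in T cells and 0.104 in iNKT cells, a ratio of 0.563 that ranged from 0.301 to 1.30 with 1 array left out (0.714 over the 6534 genes detected on T cell arrays). Other cells in the iNKT samples could add to the iNKT count. The labels give no measure of how completely Dicer was lost in either cell type.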

How the results depend on the processing

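The myeloid covariate, the fits without the 2 arrays with the fewest detected probes (WT stage 1-2 replicate 1 and WT stage 3 replicate 2) or without the 2 T cell arrays that did not detect Eif2s3y, and the axes on fewer genes or with T cell arrays added were chosen only after the data were seen. With 3 arrays per group 6% of 1.5-fold and 56% of 2-fold changes were recovered in simulated data, and the cause of the changes given here was not tested unless the setting itself shows it. A replicate block kept the counts: 192 genes for KO iNKT against WT stage 1-2, 1952 against stage 3, 159 against both, 11 for KO against WT T cells, 1308 for stage 3 against stage 1-2, 1575 for WT iNKT against WT T cells, 8 for the difference of the KO effects and 57 of 57 list shifts; 176 of the 206 genes of the first comparison were shared. The stricter filter gave 229 and testing every probe 278 genes in that comparison. Of 225 results for named genes, 224 kept direction and call with the stricter filter, 218 with the block, 220 with trend and robust, 213 with the authors' normalized table, 211 with quantile normalization without background correction, 209 with array weights, 204 without a filter, 191 in fits of the compared groups alone and 164 with median scaling. The axis and the seed test: no axis had the 20 genes it needs under median scaling or without a detection filter, and the planned test of microRNA seed sites was not run; elsewhere the KO position was -0.171 to -0.0341 with 1 array left out, 0.0527 on rising and -0.156 on falling genes alone and -0.0473 with T cell arrays added.

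Median scaling gave 6 genes for KO iNKT against stage 1-2, 818 against stage 3, 5 against both, 2 for KO T, 496 for stage 3 against stage 1-2, 916 for WT iNKT against WT T and 0 for the difference of the effects (limma, 239 at an unadjusted p under 0.05). It moved the median of all genes to 0.20 in the first comparison, 0.16 in the second and 0.25 for the difference; relative to that median all 57 list shifts kept their sign, and Ddx58 turned to 0.0202. List medians changed in size: that of ribosomal protein genes in KO against WT T cells went from -0.19 to -0.65. That of early and type 2 genes in stage 3 against stage 1-2 cells went from -0.63 to -0.16. For the difference of the KO effects, that of type 17 genes went from -0.52 to -0.04 (-0.29 relative to all genes). Quantile normalization without background correction and the authors' table each gave 28 genes for KO T and 5 for the difference. Without a filter these were 18 and 1. A change of at least 2-fold left 1071 genes against stage 3, 100 against both, 747 for stage 3 against stage 1-2 and 721 for WT iNKT against WT T. Trend and robust gave 26 for KO T. Fits of the compared groups alone gave 14 for KO iNKT against stage 1-2, 32 against both, 17 for KO T and 804 for stage 3 against stage 1-2. Array weights gave 553, 391, 144 and 92 for KO iNKT against stage 1-2, against both, KO T and the difference, with Dicer1 at -0.0722 in iNKT cells and -0.0552 for the difference. With the mean of both WT stages as reference KO iNKT cells differed in 1215 genes and the effects in 338, with Dicer1 at -0.38 and -0.32. With stage 3 as reference the effects differed in 1198 genes, with Cd163l1 at 0.0735 and Dicer1 at -0.79. With stage 1-2 alone as the WT iNKT group, Klre1 stood at -0.0133 and Dicer1 at -0.19 against WT T cells. With an estimated correlation 13 of 57 list shifts remained, 10 up and 3 down.

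With 1 array left out the counts ranged from 71 (KO replicate 1) to 461 (KO replicate 3) for KO iNKT against stage 1-2, 58 to 389 (the same arrays) against both, 0 (WT T replicate 1) to 8 (KO T replicate 1) for KO T, and 0 (KO iNKT replicate 2) to 118 (KO iNKT replicate 3) for the difference. They ranged from 1450 to 2139 against stage 3, 1005 to 1275 for stage 3 against stage 1-2 and 1106 to 1661 for WT iNKT against WT T. Dicer1 ranged from -0.0717 to 0.26 in iNKT cells against stage 1-2, -0.17 to 0.0766 in T cells and -0.0137 to 0.31 for the difference. Without the 2 arrays with the fewest detected probes the difference gave 0 genes (limma, 617 at an unadjusted p under 0.05), with Dicer1 at -0.0134 there and at -0.0723 in iNKT cells, and KO iNKT against stage 1-2 gave 189 genes, 131 of them among the 206. Without the T cell arrays that lacked Eif2s3y, 0 genes passed for KO T (limma, 245 at an unadjusted p under 0.05).

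The myeloid covariate, which follows the groups, gave 1 gene for KO iNKT against stage 1-2, 2 against stage 3, 1 against both, 24 for stage 3 against stage 1-2, 161 for WT iNKT against WT T and 0 for the difference (limma, 394 at an unadjusted p under 0.05), and 10 for KO T as before. Of 225 named results 68 kept direction and call. Against stage 1-2, Ifitm3 turned to -0.73, Cd74 to -0.46, H2-Aa to -0.80 and Cd163l1 to 0.10. Against stage 3, S100a9 turned to -2.55, Ltf to -1.65, Camp to -1.30, S100a8 to -0.91, Lcn2 to -3.20, Dntt to -0.17, Arpp21 to -0.55, Cd74 to -0.0254, H2-Ab1 to -1.04, H2-Aa to -1.06, Igf2 to -2.96 and Anxa1 to -1.07, and Zap70 to 0.14, Icos to 0.60, Snai3 to 0.63 and Eef2 to 0.66. For stage 3 against stage 1-2, S100a9 turned to 0.90, Ltf to 0.30, Camp to 0.28, Lcn2 to 1.54 and H2-Aa to 0.26. S100a9 turned to -1.09 for WT iNKT against WT T, and H2-Aa to -0.56 for the difference. S100a8 and S100a9 are members of the list that gives the covariate, so their turns are no separate result.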

Other observations

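None of the tests in this part was chosen only after its result was seen. Some fixed lists shifted in no comparison. Among 14 small RNA pathway genes 3 rose in WT stage 3 against stage 1-2 cells (median 0.29, adjusted p = 0.129), and 3 rose and 5 fell in KO iNKT against WT stage 3 cells (median -0.12, adjusted p = 0.597). Of 18 p53 targets and BH3 genes, the mediators of cell death after DNA damage, 5 rose and 1 fell in WT iNKT against WT T cells (median 0.37, adjusted p = 0.11), and none changed in KO iNKT against WT stage 1-2 cells (median 0.11, adjusted p = 0.761). Of 10 cholesterol synthesis genes 2 rose in KO iNKT against WT stage 3 cells (median 0.33, adjusted p = 0.303). Of 13 regulatory T cell genes 5 rose and 2 fell in that comparison (median 0.09, adjusted p = 0.522), and Gpr83 rose by 1.22 in KO iNKT against WT stage 1-2 cells (adjusted p = 0.00958), a call lost without KO replicate 1 (0.0571). Of 3 epithelial and stromal genes 2 rose against WT stage 3 cells (median 0.57, adjusted p = 0.0987). None of 8 probed erythroid genes passed the detection filter, so that list was not tested. Of lists that shifted elsewhere, cytokine receptors, glycolysis genes and chemokine receptors did not shift in KO iNKT against WT stage 1-2 cells.

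The sex-linked genes passed in no comparison; in KO iNKT against WT stage 1-2 cells Xist had a change of -0.37 (adjusted p = 0.772) and Eif2s3y of -0.29 (0.922). Eif2s3y was not detected on WT T replicate 1 (log2 intensity 4.31) and KO T replicate 3 (4.33), and Xist was highest on the same pair of arrays (6.40 and 6.99). On the other arrays Eif2s3y stood at 5.31 (KO iNKT replicate 3) to 8.60. A list's median and mean differed in sign in 10 cases. In KO iNKT against WT stage 1-2 cells these were early and type 2 genes (0.13 and -0.07) and survival genes (0.02 and -0.05), against WT stage 3 cells type 17 genes (-0.14 and 0.16), and in KO against WT T cells survival genes (-0.02 and 0.05) and type I interferon genes (0.06 and -0.02). In WT stage 3 against stage 1-2 cells it was type I interferon genes (0.03 and -0.14), and in WT iNKT against WT T cells double-positive thymocyte genes (0.68 and -0.06). For the difference of the KO effects they were survival genes (0.01 and -0.11), chemokine receptors (0.03 and -0.14) and epithelial and stromal genes (-0.14 and 0.02). No list with such a difference was called.

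Other splits of the same arrays were counted for each comparison. For KO iNKT against WT stage 1-2 cells the real split gave 206 genes and the highest other 84, and against WT stage 3 cells they gave 2047 and 0 (limma). For KO against WT T cells they gave 10 and 1, and for WT stage 3 against stage 1-2 cells 1377 and 0 (limma). In each of these 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. For WT iNKT against WT T cells 1 of 84 splits, the real one, gave as many genes (1614, highest other 1445). Most of the other splits put T cell and iNKT arrays in the same group. This adds to the spread within groups and lowers the count, so that this share does not exclude chance. For the genes changed against both WT stages 2 of 84 splits gave as many as the real 163, the real one included. The other, with 1032 genes, named the 3 WT stage 3 arrays as the odd group, which is the structure of the stages. The next highest gave 71. Many of the splits moved WT stage 3 arrays into another group, where the stage difference adds to the spread within groups and lowers the count. For that reason the share of splits does not exclude chance here.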
